A study of Drosophila melanogaster with 8 samples.

How the data were processed

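Total RNA from eye-antennal imaginal discs of wandering third-instar Drosophila melanogaster larvae was measured on 8 Affymetrix Drosophila arrays. Each sample held 100 pairs of discs, and biotin-labelled RNA was made from 100 ng of total RNA by in vitro transcription after repeated rounds of cDNA synthesis, per the labels' protocols. The eyeless driver ey-GAL4 expressed UAS transgenes in 4 genotypes with 2 biological replicates each. The lacZ group carried UAS-lacZ on both responder chromosomes, the vg group UAS-vg with UAS-lacZ, the simj group UAS-simj with UAS-lacZ, and the vg_simj group UAS-vg with UAS-simj. The number of UAS-lacZ copies therefore fell from 2 in lacZ to 1 in vg and in simj and to 0 in vg_simj, and cannot be separated from genotype. Whether same-numbered replicates shared a day or batch was not given in the sources used here.

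The deposited values are linear intensity values, MAS5 signals with 1 value per probe set and array, per the labels' processing tool field. The MAS5 version was not stated. On every array the mean without the lowest and highest 2% of probe sets was 500, so each array had been scaled by a single factor, with no equalising of distributions between arrays. Median signals lay between 36.5 and 46.3, and 75th percentiles between 546 and 566. Detection calls were not used here, so a low signal could not be told from background. The number of arrays, 2 per group, limits the precision of every value.

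Of 18952 probe sets, 183 were array controls. The platform annotation gave 1 gene symbol to 13647 probe sets, several to 402 and none to 4903, and symbols were updated through the reference gene table, which lacked the gene of 103 single-symbol probe sets. Only probe sets with 1 symbol were named. The gene sd, the DNA-binding partner of vg, had no probe set with its symbol and was not analysed here. Values were taken as log2(signal + 2.8), the pseudocount being the 10th percentile of all values, which understates the fold of dim genes. Control probe sets were left out, and a probe set was kept where its signal exceeded the array's median on at least 2 of the 8 arrays. This left 10205 probe sets, of which 8759 had 1 symbol and stood for 8034 genes.

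One group-means model over all 8 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with 4 residual and 3.84 prior degrees of freedom. The 6 contrasts were each transgene group against lacZ, vg_simj against vg, vg_simj against simj, and the interaction, which is the vg effect with simj minus the vg effect without it. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within a contrast, and calls were made at an adjusted p under 0.05. Log2 changes are given with their standard error, and signals as mean ± SD of 2 arrays. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333, so every test rests on the spread shared across probe sets and groups.

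Lists of genes for disc patterning, signalling pathways, cell processes and markers of other tissues were fixed in advance. Of the 35 lists, 34 had the minimum of 3 measured members and were tested with camera at a preset correlation of 0.01, on 1 probe set per gene (the one with the highest mean), with adjustment over all lists and contrasts. Not every list call is reported, and each reported call is given beside the adjusted p with an estimated correlation. Many lists share members: 11 of 11 direct targets of Vestigial and Scalloped, 15 of 31 wing, 9 of 12 retinal determination and 14 of 26 photoreceptor genes were also in another list. So were 10 of 13 morphogenetic furrow and 18 of 19 antennal genes. Calls of lists that share members are not separate evidence. Of the 66 list calls none held with an estimated correlation, where the smallest adjusted p was 0.532 and the count of calls was 0. Of the 4 genes named always, vg, simj, sd and ey, sd could not be. Otherwise a gene was named as among the 10 largest rises or falls that passed the test, had non-overlapping arrays and a higher group above the median signal, as among the 4 members with the smallest p of a list that was called or had at least 3 called members, or as among such 4 of the wing, retinal, photoreceptor, Hox and NuRD lists whatever they showed. Genes outside this rule are identified as chosen after their values were seen.

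The design, lists, naming rule and the alternatives were fixed before the data were examined, except for a pseudocount of 64 and lists without vg and simj, chosen after seeing the data. The alternatives were 0.1 and 4 times the pseudocount, no filter and a stricter filter (above the 75th percentile), quantile normalization and median centring, no intensity trend, 1 probe set per gene, a 2-fold minimum, the replicate number as a block, only the groups compared, and each array left out in turn. The code was tested on data simulated for vg against lacZ in 10 simulations, each with 200 of 10205 probe sets changed. It found 41.8% of those changed by 1 on the log2 scale, 74.6% by 2 and 86.0% by 3, with 3.70% false among the calls. A list of 25 genes shifted by 0.5 was called in 10 of 10 simulations and an unshifted one in 0. The simulated probe sets varied independently of each other, so this does not show how often unshifted lists of correlated genes are called.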

Results

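Gene expression was measured in eye-antennal discs, the larval epithelia that form the adult eye, antenna and head capsule, in which the ey-GAL4 driver expressed vestigial (vg), simjang (simj), both, or lacZ as a control. The gene vg encodes the transcriptional cofactor that selects wing identity together with scalloped, and simj encodes the p66 subunit of the NuRD chromatin-remodelling complex. The series concerns the change of eye discs toward another disc fate by these transgenes. Each of the 4 groups had 2 arrays. Correlations of log2 signals across probe sets were 0.955 to 0.971 between replicates and 0.912 to 0.963 between arrays of different groups, over genes that are not independent replicates.

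The vg signal rose from 28.7 ± 0.990 (SD, n = 2) in lacZ discs to 246 ± 17.6 in vg and 417 ± 21.9 in vg_simj, and stood at 19.4 ± 3.96 in simj. The log2 change was 2.98 ± 0.27 (SE) in vg against lacZ (limma, adjusted p = 0.00419) and 4.25 ± 0.27 in vg_simj against simj (adjusted p = 0.000315), and another vg probe set rose by 4.41 and 5.63. The simj signal was 603 ± 176 in lacZ, 637 ± 59.4 in vg, 1162 ± 140 in simj and 994 ± 117 in vg_simj, higher on each simj-carrying array than on any other. Its log2 change of 0.97 ± 0.22 in simj against lacZ did not pass the test (adjusted p = 0.180), nor did 0.64 ± 0.22 in vg_simj against vg (adjusted p = 0.342). The driver gene ey, itself expressed in the eye primordium, had signals of 548 ± 115, 560 ± 26.8, 344 ± 14.1 and 616 ± 92.6 in lacZ, vg, simj and vg_simj, with no call (adjusted p = 0.338 in simj against lacZ). Whether the probe sets of vg and simj lie within the transgenes was not tested here.

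**Figure D1:**
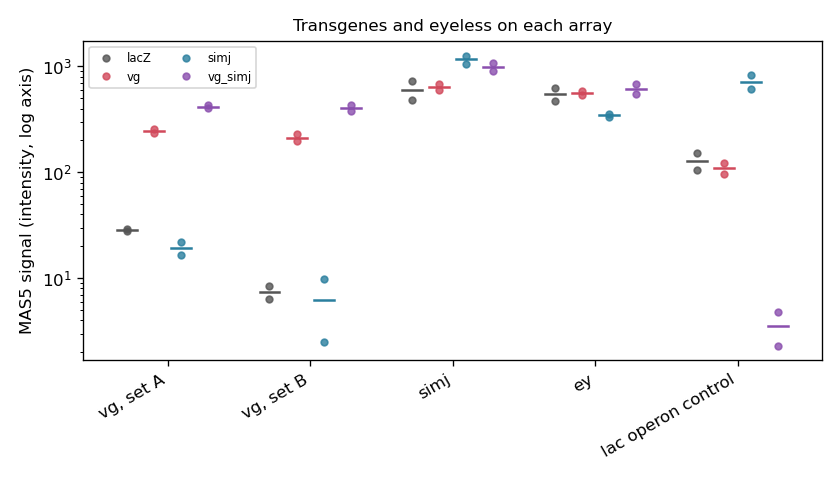
Signals of both vg probe sets, simj, ey and 1 of 4 control probe sets of the bacterial lac operon on each array, as MAS5 intensity on a log axis; points are arrays and bars are means of 2 arrays. The vg signal was 28.7 in lacZ and 246 in vg, and the lac operon signal 128 in lacZ, 110 in vg, 719 in simj and 3.55 in vg_simj.

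The first comparison asked what vg alone did to eye discs. The largest rises were in Cyp4p2, a cytochrome P450 gene, from a signal of 15.3 ± 5.09 to 1754 ± 23.5 (SD, n = 2; log2 change 6.63 ± 0.31), and in skl, a cell death activator of the reaper family, from 20.6 ± 2.76 to 1146 ± 131 (5.62 ± 0.30). Then came Rnf11, from 65.3 ± 30.8 to 2192 ± 177 (5.09 ± 0.31). The zinc transporter gene Zip102B rose by 4.74 ± 0.58, and Ilp8, the insulin-like peptide that damaged or overgrowing discs release, rose from 16.9 ± 18.0 to 259 ± 58.1 (4.10 ± 0.65, adjusted p = 0.0359). CG6912, CG32444, CG34247 and lncRNA:CR32027 rose by 1.95 to 3.14. Wing genes other than vg itself did not pass the test: nub, a wing-pouch POU factor, had a log2 change of 1.39 ± 0.36 (adjusted p = 0.187), bi, the T-box gene optomotor-blind, 0.47 ± 0.14 (adjusted p = 0.262), and vvl -0.85 ± 0.20 (adjusted p = 0.152).

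Among eye genes, none of the 26 measured photoreceptor genes passed in vg against lacZ (mean log2 change 0.06, adjusted p = 0.282 and adjusted p = 0.938 with an estimated correlation). The receptor gene of R7 photoreceptors, sev, stood at -1.20 ± 0.24 (adjusted p = 0.0853). The 12 retinal determination genes had a mean of -0.01 (adjusted p = 0.983 and adjusted p = 0.986 with an estimated correlation). The 11 measured direct targets of Vestigial and Scalloped lay higher as a list (mean 0.47, adjusted p = 0.00922, but adjusted p = 0.706 with an estimated correlation), although 1 member, the transgene vg itself, was called and 4 passed when adjusted over the list alone. With vg taken out, a test chosen after the values were seen, the other 10 had a mean of 0.22 and were not called (adjusted p = 0.0945, adjusted p = 0.788 with an estimated correlation). Without lacZ replicate 2 the list of 11 was no longer called either. Positive means were also called for the Hedgehog (0.18), Wingless (0.48) and Notch (0.24) lists at adjusted p = 0.0018, adjusted p = 0.00438 and adjusted p = 0.0320, against adjusted p = 0.710, adjusted p = 0.706 and adjusted p = 0.786 with an estimated correlation. No member of the Hedgehog or Notch list was called, and vg was the called member of the Wingless list, whose mean fell to 0.22 without vg (adjusted p = 0.0547, adjusted p = 0.800 with an estimated correlation).

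The largest falls with vg were in Lectin-galC1 (-4.65 ± 0.78), Amnionless (-4.13 ± 0.64), CG1545 (-4.06 ± 0.46) and CG14275 (-3.50 ± 0.44). This order depended on the pseudocount, since Amnionless (3.65 ± 0.354) and CG1545 (4.20 ± 1.13) lay near background in vg. With a pseudocount of 64 the 4 changes were -2.37, -1.39, -1.38 and -2.75, and the Amnionless call was lost (limma, adjusted p = 0.0941). Most other named falls, among them PPO2 (-2.58), cu (-2.37), GstE14 (-2.33) and sad (-2.16), were then larger than those of Amnionless and CG1545. Genes of blood cells and of the ring gland, the larval endocrine organ that makes ecdysone and lies next to the brain, were also among the falls. The gene PPO2, a prophenoloxidase of crystal cells, fell from 1572 ± 123 to 232 ± 157 (-2.93 ± 0.44) and Hml, a plasmatocyte gene, fell by 2.37 ± 0.33. The ecdysone synthesis genes sad, from 5949 ± 629 to 1287 ± 160 (-2.21 ± 0.20), nvd (-2.03 ± 0.20) and dib (-1.88 ± 0.27) fell. So did GstE14 (-2.64 ± 0.43), also of ecdysone synthesis, ouib (-2.58 ± 0.29), a zinc-finger activator of spok, and the cholesterol transporter gene Npc1a (-1.32 ± 0.12). Of the 11 measured ring gland genes 6 fell, and 8 when adjusted over the list alone (mean -1.54, adjusted p = 1.96e-11, adjusted p = 0.532 with an estimated correlation). Of 23 haemocyte genes 2 fell over all probe sets, while 11 fell and 1 rose when adjusted over the list alone (mean -1.05, adjusted p = 1.72e-08, adjusted p = 0.532 with an estimated correlation). CG17928, cu and CG30471 fell, with changes from -2.40 to -2.48.

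Salivary gland genes, which hand-dissected discs can carry along, had a positive mean in vg of 1.91 (adjusted p = 0.00734, adjusted p = 0.757 with an estimated correlation), with 0 of 13 members called. Their replicates lay far apart, with ng3 at 1563 ± 2187 in vg, and without vg replicate 1 the list was no longer called. Neuroblast genes had a mean of 0.56 (adjusted p = 0.0470, adjusted p = 0.757 with an estimated correlation; 0 of 11 called). In total limma called 79 probe sets in vg against lacZ, 26 higher and 53 lower, standing for 55 named genes. The count was 38 without lacZ replicate 1, 26 without lacZ replicate 2, 48 without vg replicate 2 and 52 without either simj array. Of the 25 gene calls under the naming rule, 9 held with each array left out and under each alternative that kept their probe set: Cyp4p2, skl, Rnf11, CG6912, vg, cu, sad, nvd and Npc1a. The stricter filter left out probe sets with lower signals, such as that of vg, and so did not test them.

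**Figure D2:**
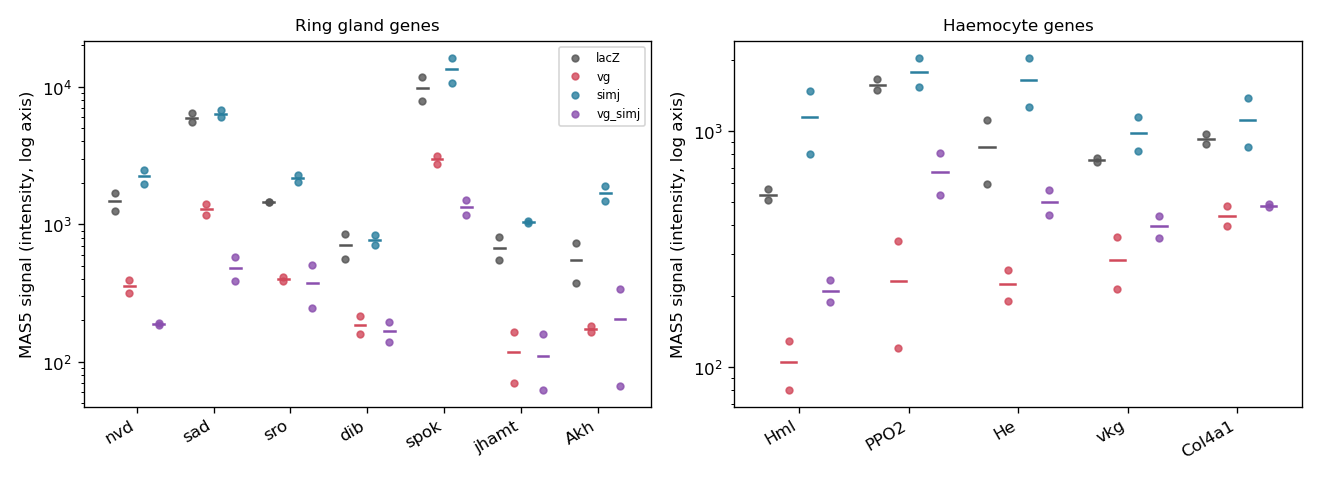
Signals of ring gland genes (left) and haemocyte genes (right) on each array, as MAS5 intensity on a log axis; points are arrays and bars are means of 2 arrays. The sad signal was 5949 in lacZ and 6373 in simj against 1287 in vg and 484 in vg_simj.

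The second comparison asked what simj alone did. Photoreceptor genes were lower as a list: gl, the zinc-finger factor required for photoreceptor development, fell from 2405 ± 21.8 to 992 ± 89.2 (SD, n = 2; log2 change -1.28 ± 0.13, adjusted p = 0.0129), a call lost without lacZ replicate 2 and without either simj array. The values of phyl (-1.12 ± 0.18), sev (-1.43 ± 0.24) and lz (-1.07 ± 0.18) had an adjusted p of 0.0579, 0.0666 and 0.0673. Of 26 members 1 fell, 19 when adjusted over the list alone, and 24 had a negative change (mean -0.81, adjusted p = 5.47e-18, adjusted p = 0.661 with an estimated correlation). All 12 retinal determination genes had a negative change (mean -0.61, adjusted p = 7.37e-09, adjusted p = 0.661 with an estimated correlation), and 7 passed when adjusted over the list alone but 0 over all probe sets. The values were danr at -1.13 ± 0.18, dan at -1.05 ± 0.18 and so at -0.86 ± 0.15. The Notch targets E(spl)m4-BFM, from 4693 ± 44.2 to 2290 ± 180 (-1.04 ± 0.12), and E(spl)mdelta-HLH (-0.98 ± 0.12) fell.

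The Notch (mean -0.29, 2 of 23 members fell, adjusted p = 1.46e-06), morphogenetic furrow (-0.36, 0 of 13, adjusted p = 0.000828), antennal (-0.30, 0 of 19, adjusted p = 0.00937) and neuronal (-0.38, 0 of 28, adjusted p = 0.0157) lists were called lower in simj. With an estimated correlation these had adjusted p = 0.706, adjusted p = 0.706, adjusted p = 0.767 and adjusted p = 0.757. The antennal and neuronal calls were each lost without lacZ replicate 1 and without simj replicate 2. Of the antennal genes 18 of 19 were also in another list, as were 10 of 13 furrow genes. The antennal list shares dan and danr with the retinal determination list, and the furrow list shares so with it. The antennal and furrow calls are thus not separate from those of the eye genes. The neuronal adhesion and guidance genes klg (-1.88 ± 0.29) and gogo (-1.42 ± 0.20) fell, as did the glutamate receptor gene Ekar, from 613 ± 11 to 164 ± 2.90 (-1.89 ± 0.17). Further falls were in miple1, which encodes a midkine family growth factor (-1.32 ± 0.17), rdo, qua, CG13840, CG11382, CG5653 and CG9150.

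Among the rises in simj discs were Cyp4g1, an oenocyte cytochrome P450 gene, from 9.80 ± 12.3 to 794 ± 110 (6.44 ± 0.89), Rnf11, from 65.3 ± 30.8 to 4176 ± 1242 (5.98 ± 0.31), CG12522, CG32071, CG6282, CG32073, CG15879, CG5704, CG5326 and the mitochondrial ribosomal gene mRpL45, from 236 ± 0.283 to 704 ± 74.0. Another Rnf11 probe set had a change of 0.67 in simj (adjusted p = 0.622), so the rise with simj was not shared by both probe sets. Tissue markers had positive means in simj: salivary gland 2.48 (adjusted p = 2.68e-05, adjusted p = 0.706 with an estimated correlation), haemocyte 0.34 (adjusted p = 0.00192, adjusted p = 0.664 with an estimated correlation) and ring gland 0.38 (adjusted p = 0.0211, adjusted p = 0.710 with an estimated correlation), with 0 members called. The innate immunity list had a mean of 0.39 (adjusted p = 0.0103, adjusted p = 0.661 with an estimated correlation). The ring gland call was lost without lacZ replicate 1 or simj replicate 2, the haemocyte call without simj replicate 2, the salivary call without simj replicate 1 and the immunity call without lacZ replicate 2.

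None of the 6 measured NuRD genes, simj among them, passed over all probe sets in simj, and 1 rose when adjusted over the list alone (mean 0.09, adjusted p = 0.730, adjusted p = 0.938 with an estimated correlation). Without simj the list had a mean of -0.09 (adjusted p = 0.684, adjusted p = 0.964 with an estimated correlation). The smallest p was that of simj itself, and HDAC1 was at -0.27 ± 0.16 and Mi-2 at 0.16 ± 0.14. In total limma called 42 probe sets in simj against lacZ, 15 higher and 27 lower, standing for 29 named genes. The count was 1 without lacZ replicate 2, 26 without lacZ replicate 1, 2 without simj replicate 1, 5 without simj replicate 2 and 12 without either vg_simj array. Of the 23 gene calls under the naming rule 1 held with each array left out, that of Rnf11, while the photoreceptor, retinal determination, furrow and Notch list calls held with each.

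The third comparison set discs with both transgenes against lacZ. Wing genes rose: nub from 127 ± 67.8 to 862 ± 114 (SD, n = 2; log2 change 2.84 ± 0.36, adjusted p = 0.00542) and bi from 1156 ± 154 to 2417 ± 52.0 (1.07 ± 0.14, adjusted p = 0.0061). The wing-disc cytochrome P450 gene Cyp310a1 rose from 220 ± 51.5 to 924 ± 63.3 (2.07 ± 0.40, adjusted p = 0.0332). The BMP ligand gene dpp rose from 800 ± 12.4 to 1444 ± 68.4 (0.85 ± 0.12, adjusted p = 0.00909). The gene Dll, a distal appendage selector, rose by 0.75 ± 0.15 (adjusted p = 0.0402), with another Dll probe set at 0.47 (adjusted p = 0.316). Of 31 wing patterning genes 4 rose and 1 fell, 6 and 1 when adjusted over the list alone (mean 0.55, adjusted p = 0.00207, adjusted p = 0.719 with an estimated correlation). Of the 11 direct targets of Vestigial and Scalloped 5 rose (mean 0.91, adjusted p = 0.00182, adjusted p = 0.664 with an estimated correlation), and 5 rose and 2 fell when adjusted over the list alone. Both lists hold vg itself, nub, bi and Cyp310a1. All 11 direct targets are also in another fixed list, so the 2 list calls are not separate evidence. Without vg, 3 of 30 wing genes rose and 1 fell (mean 0.45, adjusted p = 0.00961, adjusted p = 0.800 with an estimated correlation), and 4 of 10 direct targets rose (mean 0.63, adjusted p = 0.0213, adjusted p = 0.777 with an estimated correlation). The nub call was lost without vg_simj replicate 2 (adjusted p = 0.0549), as was the wing list call. The dpp call was lost without either lacZ array or vg_simj replicate 2, the Cyp310a1 call when any lacZ or vg_simj array was left out and the Dll call when any array was, while bi kept its call throughout.

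Photoreceptor and neuronal genes fell in vg_simj discs. The receptor gene sev fell from 460 ± 34.1 to 50.5 ± 14.1 (-3.14 ± 0.24, adjusted p = 0.000581) and onecut, a homeodomain gene of photoreceptors and neurons, from 194 ± 62.6 to 24.6 ± 4.38 (-2.81 ± 0.31). Also lower were chp, which encodes chaoptin of photoreceptor membranes, from 585 ± 47.9 to 119 ± 5.44 (-2.27 ± 0.25), and gl from 2405 ± 21.8 to 853 ± 81.8 (-1.5 ± 0.13). Of 26 photoreceptor genes 10 fell, 16 when adjusted over the list alone (mean -0.94, adjusted p = 6.21e-11, adjusted p = 0.687 with an estimated correlation). Of 28 neuronal genes 6 fell, 9 when adjusted over the list alone (mean -0.79, adjusted p = 3.33e-06, adjusted p = 0.706 with an estimated correlation), and these included Ank2, a neuronal ankyrin gene (-2.49 ± 0.28), Appl, the amyloid precursor homologue (-2.40 ± 0.28), and nrv3 (-1.37 ± 0.19). The 12 retinal determination genes had a mean of -0.20 (adjusted p = 0.0921, adjusted p = 0.786 with an estimated correlation) and 1 fell, dan (-0.92 ± 0.18, adjusted p = 0.0380), a call lost when any array other than vg_simj replicate 2 was left out.

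**Figure D3:**
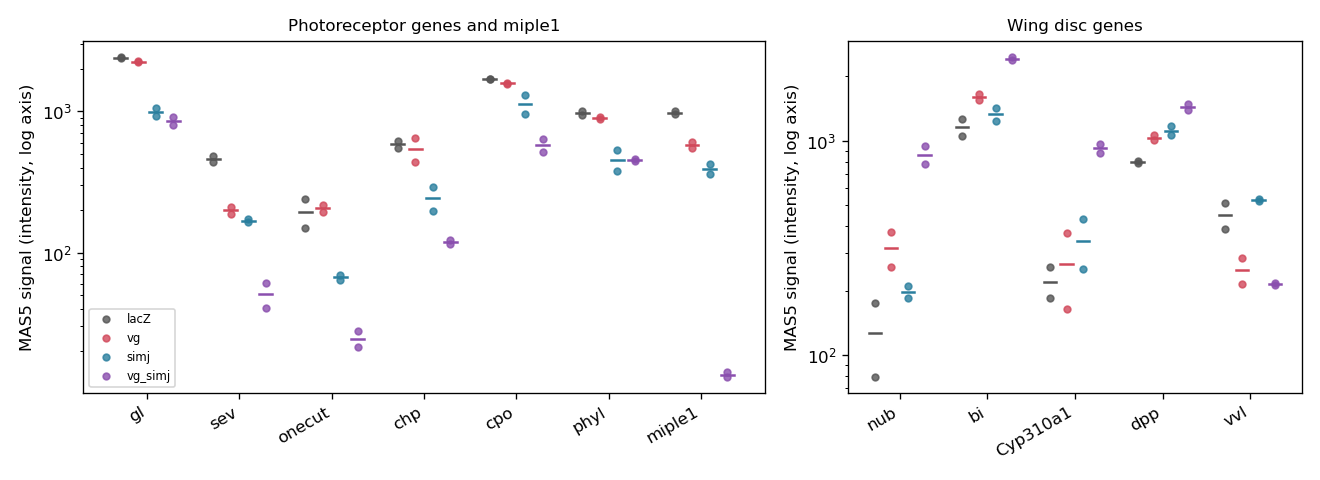
Signals of photoreceptor genes with miple1 (left) and of wing disc genes (right) on each array, as MAS5 intensity on a log axis; points are arrays and bars are means of 2 arrays. In vg_simj discs sev stood at 50.5 and miple1 at 13.7, against 460 and 981 in lacZ, and nub at 862 against 127.

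The largest falls in vg_simj were in CG15919 (-6.02 ± 0.79), mthl8, a methuselah-like receptor gene, from 426 ± 16.7 to 4.30 ± 1.13 (-5.92 ± 0.25, or -2.84 with a pseudocount of 64, since the signals lie near background), and miple1, from 981 ± 33.1 to 13.7 ± 0.778 (-5.90 ± 0.17, adjusted p = 8.5e-06). CG31207, CG4408, nolo, Tsp68C, CG34296, Amnionless and Lectin-galC1 fell, with changes from -3.74 to -4.12. CG13460, CG14852, Rnf11, Cyp4p2, skl, Zip102B and AstC rose by 4.54 to 9.06, but CG13460 (8565 ± 7622) and CG14852 (2540 ± 1192) differed widely between replicates. The signal of CG13460 was also high in simj alone (12425 ± 6235). The antifungal peptide gene Drs rose from 38.0 ± 12.1 to 2088 ± 1775 (5.39 ± 0.59) and Jig from 8.25 ± 9.26 to 923 ± 724. In the JNK and tissue damage list Ilp8 rose to 650 ± 285 (5.37 ± 0.65), while egr, the TNF ligand gene, fell from 933 ± 9.40 to 373 ± 9.83 (-1.32 ± 0.13) and its pathway gene Traf4 fell by 1.13 ± 0.17. The activin ligand gene Actbeta fell by 2.20 ± 0.30.

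Beside the eye and wing genes, lists drawn up as markers of attached tissues moved in vg_simj. Whether the discs themselves express members of these lists was not tested. Of 11 ring gland genes 7 fell, 9 when adjusted over the list alone (mean -1.97, adjusted p = 1.1e-10, adjusted p = 0.532 with an estimated correlation). Among them were sad at 484 ± 135 (-3.64 ± 0.20), nvd at -2.92 ± 0.20 and spok at -2.87 ± 0.26. Haemocyte genes had a mean of -0.55 (1 of 23 fell, srp at -1.72 ± 0.34, and 5 when adjusted over the list alone; adjusted p = 0.000828, adjusted p = 0.661 with an estimated correlation). Salivary gland genes had a mean of 3.14 (0 of 13 called, adjusted p = 0.000117, adjusted p = 0.710 with an estimated correlation). In the tracheal list peb (-1.47 ± 0.23) and ana (-0.87 ± 0.17) fell (mean -0.39, adjusted p = 0.0224, adjusted p = 0.710 with an estimated correlation), a list call lost without vg_simj replicate 1. The 45 cell cycle genes had a mean of 0.23, with 39 positive and 0 called (adjusted p = 8.82e-06, adjusted p = 0.706 with an estimated correlation), and mad2 at 0.53 ± 0.12.

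In total limma called 340 probe sets in vg_simj against lacZ, 106 higher and 234 lower, standing for 286 named genes. The count was 159 without lacZ replicate 1, 156 without lacZ replicate 2, 168 without vg_simj replicate 1 and 166 without vg_simj replicate 2. Of 44 gene calls under the naming rule 23 held with each array left out, and 22 under each alternative that kept their probe set too. Among them were sev, gl, onecut, chp, Ank2, Appl, bi, miple1, mthl8, egr, skl, sad, nvd and spok. Those with lower signals, such as mthl8, were not tested under the stricter filter.

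**Figure D4:**
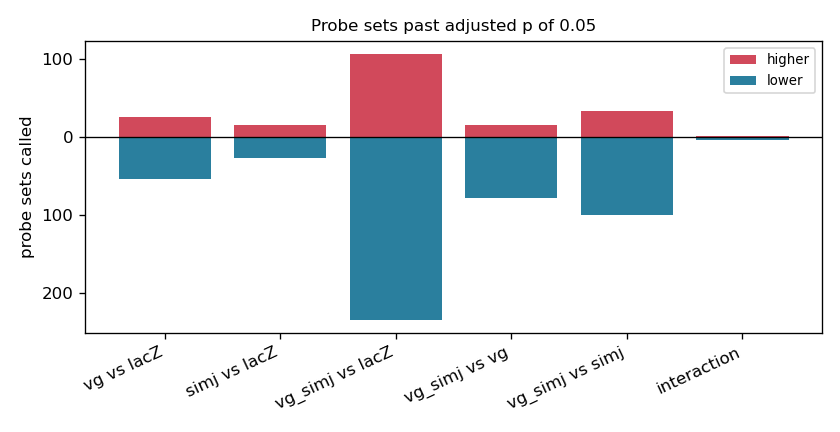
Probe sets called by limma at an adjusted p under 0.05 in each contrast, higher above the line at 0 and lower below it. The highest count was 340 in vg_simj against lacZ, and the interaction had 5.

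The fourth comparison asked what simj added to vg. The largest falls were in miple1 (578 ± 43.6 to 13.7 ± 0.778, -5.14 ± 0.17), mthl8 (-4.95 ± 0.25), nolo (-3.56 ± 0.34) and CG31207 (-3.21 ± 0.18). Eye and neuronal genes also fell. The gene onecut fell from 206 ± 16.3 in vg to 24.6 ± 4.38 in vg_simj (SD, n = 2; log2 change -2.94 ± 0.31), Ank2 from 1318 ± 148 to 213 ± 53 (-2.63 ± 0.28) and Appl from 1362 ± 117 to 228 ± 68.0 (-2.59 ± 0.28). The neuronal zinc-finger gene nerfin-1 fell by 2.83 ± 0.29 and gl from 2250 ± 12.2 to 853 ± 81.8 (-1.40 ± 0.13, adjusted p = 0.00507). Of 26 photoreceptor genes 10 fell, 17 when adjusted over the list alone (mean -1.0, adjusted p = 5.56e-21, adjusted p = 0.653 with an estimated correlation), and 6 of 28 neuronal genes (mean -0.87, adjusted p = 1.13e-09, adjusted p = 0.661 with an estimated correlation). The 23 Notch genes had a mean of -0.30 (adjusted p = 6.9e-06, adjusted p = 0.706 with an estimated correlation), and E(spl)mdelta-HLH fell by 0.82 ± 0.12. The genes kat-60L1 and klg also fell.

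No wing patterning gene passed between vg and vg_simj. The values were 1.89 ± 0.40 for Cyp310a1 (adjusted p = 0.10), 1.45 ± 0.36 for nub (adjusted p = 0.159), 0.60 ± 0.14 for bi (adjusted p = 0.144) and 2.58 ± 0.65 for nab (adjusted p = 0.165). Of 31 wing genes 4 passed when adjusted over the list alone (mean 0.36, adjusted p = 0.0231, adjusted p = 0.757 with an estimated correlation). The direct targets of Vestigial and Scalloped had a mean of 0.43 (0 of 11 called, adjusted p = 0.0264, adjusted p = 0.710 with an estimated correlation), and without vg itself were not called (mean 0.40, adjusted p = 0.0703, adjusted p = 0.788 with an estimated correlation). Both list calls were lost without vg replicate 1 and without vg_simj replicate 2. Rises included Drs, from 22.6 ± 2.62 to 2088 ± 1775 (6.05 ± 0.59), Jig, the cuticle genes Vajk3 (171 ± 87.8 to 1840 ± 94.7, 3.50 ± 0.33) and Vajk2 (2.14 ± 0.29), CG6282, CG6763, Ir76a, CG5002, rpk and lncRNA:CR32027. Glial genes had a mean of -0.31 (0 of 12 called, adjusted p = 0.00199, adjusted p = 0.610 with an estimated correlation). Of the ring gland genes sad fell by 1.43 ± 0.20 (1 of 11, mean -0.42, adjusted p = 0.00243, adjusted p = 0.687 with an estimated correlation). The ring gland call was lost without vg_simj replicate 2. Haemocyte genes had a positive mean of 0.50 (0 of 23 called, adjusted p = 0.0264, adjusted p = 0.710 with an estimated correlation), a call also lost without that array.

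Limma called 94 probe sets between vg_simj and vg, 16 higher and 78 lower, standing for 76 named genes. The count was 21 without vg replicate 2, 27 without vg_simj replicate 1 and 33 without vg_simj replicate 2. Of 27 gene calls under the naming rule 6 held with each array left out. Those of miple1, mthl8, CG31207, gl and nerfin-1 also held under each alternative that kept their probe set. The stricter filter left out mthl8 and CG31207.

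The fifth comparison asked what vg added to simj. Of the 26 probe sets that rose with vg alone, 12 also rose here: among these were Cyp4p2 from 15.9 ± 7.21 to 1851 ± 36.6 (SD, n = 2; log2 change 6.69 ± 0.31), skl from 30.8 ± 13.1 to 1503 ± 290 (5.53 ± 0.30) and CG6912, by 3.10 ± 0.25. The Rnf11 probe set with the largest rise in vg did not pass (0.77 ± 0.31, adjusted p = 0.265), while another rose by 2.53 (adjusted p = 0.00848). The wing genes nub (2.11 ± 0.36, adjusted p = 0.0387) and bi (0.87 ± 0.14, adjusted p = 0.0293) rose and vvl, a POU factor, fell by 1.29 ± 0.20. With vg that made 3 rises and 1 fall among 31 wing genes (mean 0.41, adjusted p = 0.0874, adjusted p = 0.802 with an estimated correlation). The direct targets of Vestigial and Scalloped were called as a list (mean 0.87, 3 of 11 rose, adjusted p = 0.00204, adjusted p = 0.664 with an estimated correlation), with each array left out too. That list holds vg, and without it 2 of 10 rose (mean 0.53, adjusted p = 0.0232, adjusted p = 0.781 with an estimated correlation). The Bearded family genes Brd (2041 ± 108 to 3358 ± 276, 0.72 ± 0.11) and Tom (0.67 ± 0.11) rose, as did Drs, Jig, Vajk3, CG14852, CG15236 and the cuticle gene TwdlE (2.78 ± 0.27).

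Retinal determination genes were higher in vg_simj than in simj as a list (mean 0.42, 11 of 12 positive, adjusted p = 0.00303, adjusted p = 0.710 with an estimated correlation). None was called over all probe sets, 5 passed when adjusted over the list alone, and ey stood at 0.83 ± 0.19 (adjusted p = 0.0941). That call was lost without vg_simj replicate 2. Photoreceptor genes were not called as a list (mean -0.13, adjusted p = 0.477, adjusted p = 0.938 with an estimated correlation), though sev (-1.71 ± 0.24) and cpo (-0.97 ± 0.17) fell. The neuronal list was lower (mean -0.40, adjusted p = 0.000919, adjusted p = 0.719 with an estimated correlation) and Ank2 fell by 1.80 ± 0.28.

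Ring gland genes fell with vg in this background also: sad from 6373 ± 551 to 484 ± 135 (-3.74 ± 0.20), nvd (-3.53 ± 0.20) and spok (-3.31 ± 0.26). In all 7 of 11 fell, and 8 when adjusted over the list alone (mean -2.35, adjusted p = 1.25e-12, adjusted p = 0.532 with an estimated correlation). Of 23 haemocyte genes Hml (-2.36 ± 0.33) and srp (-2.17 ± 0.34) fell, and 11 when adjusted over the list alone (mean -0.89, adjusted p = 7.06e-08, adjusted p = 0.532 with an estimated correlation). Muscle genes had a mean of -0.66 (0 of 17 called, 2 when adjusted over the list alone, adjusted p = 0.00648, adjusted p = 0.687 with an estimated correlation). CG12522, mthl8, Cyp4g1, Lectin-galC1, CG15919, miple1, Amnionless, CG34296 and CG14075 fell by 4.24 to 5.53.

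Limma called 133 probe sets between vg_simj and simj, 33 higher and 100 lower, standing for 110 named genes. The count was 40 without simj replicate 1, 28 without simj replicate 2, 42 without vg_simj replicate 1 and 44 without vg_simj replicate 2. Of 33 gene calls under the naming rule 11 held with each array left out: vg, Cyp4p2, skl, CG6912, TwdlE, miple1, mthl8, sad, nvd, spok and Npc1a.

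The effect of vg with and without simj was compared between pairs of groups that share no array. Of the probe sets called in each, 12 rose and 34 fell in both, against 0.0841 and 0.519 for independent lists (one-sided Fisher's exact p = 1.26e-24 and p = 9.59e-58), and the log2 changes of all probe sets had r = 0.58. For the simj effect with and without vg, 3 rose and 14 fell in both, against 0.0235 and 0.206 (one-sided Fisher's exact p = 1.42e-06 and p = 1.26e-23), with r = 0.49. Probe sets are not independent replicates in these tests, and both lists come from 1 fit with a shared spread per probe set. The counts for independent lists are thus not an exact expectation. Both pairs also exchange a UAS-lacZ chromosome for the same UAS-vg or UAS-simj one. Alleles of those stocks therefore cannot be separated from the transgene. The 46 shared calls of the vg effect were 23 without lacZ replicate 1, 21 without lacZ replicate 2, 28 without vg replicate 2, 22 without simj replicate 1, 18 without simj replicate 2, 23 without vg_simj replicate 1 and 24 without vg_simj replicate 2. The 17 of the simj effect were 0 to 11 with any array left out: 8 and 1 without lacZ replicates 1 and 2, 11 and 5 without those of vg, 0 and 2 without those of simj, and 3 without either of vg_simj.

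Against the same lacZ arrays, vg and simj shared 11 calls, 6 higher and 5 lower, where independent lists give 0.178. Unchanged groups simulated 100 times gave a mean and a maximum of 0, but such groups have hardly any calls, so this does not show what the shared arrays do to the overlap of real calls. The named ones were 1 of the Rnf11 probe sets, mRpL45 and lncRNA:CR32027, with Ykt6 chosen after its values were seen, all higher in vg and in simj. Across all probe sets the 2 effects had r = 0.156, below the 0.499 that the shared arrays gave with no effect, and a covariance of 0.0514 against 0.0986, a difference of -0.0472. The 2 lacZ arrays were not divided between the 2 effects here, so part of the shared calls may come from the shared controls.

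The interaction tested whether the effects of vg and simj added on the log2 scale. They did not for miple1, whose signal was 981 ± 33.1 in lacZ, 578 ± 43.6 in vg, 392 ± 41.6 in simj and 13.7 ± 0.778 in vg_simj (SD, n = 2; interaction -3.82 ± 0.24, adjusted p = 0.00356). Nor did they for 1 mthl8 probe set (-4.41 ± 0.35, adjusted p = 0.00931), or for 1 Rnf11 probe set, which was high with either transgene (-4.32 ± 0.44, adjusted p = 0.0222). The other probe sets of Rnf11 (-0.48 ± 0.42) and mthl8 (-1.44 ± 0.43) did not pass (adjusted p = 0.995 for each), although that of mthl8 lay in the same direction. With a pseudocount of 64, mthl8 (-1.57, adjusted p = 0.0965) and CG31207 (-1.59, adjusted p = 0.0622) did not pass. The calls of miple1 (-1.85, adjusted p = 0.0326) and Rnf11 (-3.38, adjusted p = 0.0287) held with smaller values. In CG31207 the signals were 444 ± 13.6, 272 ± 2.83, 349 ± 23 and 26.9 ± 0.424 (-2.87 ± 0.25, adjusted p = 0.0127). In miple1, mthl8 and CG31207 the vg and simj signals lay between those of lacZ and vg_simj, as the UAS-lacZ copy number does. An effect in proportion to copy number would also depart from adding on the log2 scale, so it cannot be separated from an interaction. An unnamed probe set, chosen after its values were seen, was low with either transgene (2.24 ± 0.23, adjusted p = 0.0222). Limma called these 5 probe sets, and 404 had an unadjusted p under 0.05. The count was 10 without lacZ replicate 1, 2 without lacZ replicate 2, 3 without vg replicate 2, 0 without simj replicate 1, 1 without simj replicate 2 and 2 without either vg_simj array.

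No wing, photoreceptor or retinal gene passed the interaction test, so nub, bi and sev were not shown to respond to vg differently with simj. As lists, retinal determination (mean 0.43, adjusted p = 0.000438, adjusted p = 0.706 with an estimated correlation), neuronal differentiation (-0.49, adjusted p = 9.9e-06, adjusted p = 0.706 with an estimated correlation) and ring gland genes (-0.80, adjusted p = 8.1e-07, adjusted p = 0.610 with an estimated correlation) departed from adding. The retinal call was lost without vg_simj replicate 2. The wing list had a mean of 0.21 (adjusted p = 0.470, adjusted p = 0.938 with an estimated correlation). The 3 measured Hox genes, Scr, Dfd and pb, and the 6 NuRD genes had no member called in any contrast. In vg against lacZ Scr stood at 0.90 ± 0.23 (adjusted p = 0.187) and the Hox list at a mean of 0.27 (adjusted p = 0.391, adjusted p = 0.802 with an estimated correlation).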

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

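The tests of attached tissue, array scaling, eye size, disc age and UAS-lacZ copy number below were chosen only after the results were seen, whereas the interaction tests were planned.

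The ring gland genes, 0 of 11 of them in any other list, were lower in both groups with vg, and how many of them discs themselves express was not measured here. Little shift of all probe sets was left after array scaling, with a vg effect on their median of 0.0264 on the log2 scale. Every array had already been scaled to the same trimmed mean, so this median cannot show what the scaling itself did. Carrying over less ring gland with the discs may account for the pattern. The genes jhamt and Akh, which act in parts of the gland that make no ecdysone, had a vg effect of -2.74 (95% interval -4.15 to -1.32). Both are ring gland genes themselves, so their fall is part of the pattern and no separate evidence of it. The abundant spok stood at 9806 ± 2741 in lacZ against 2962 ± 285 in vg. A loss of every loosely attached tissue cannot be told apart from a specific one, as the lists of other tissues diverged: haemocyte genes had a vg effect of -0.97 (95% interval -1.35 to -0.60), muscle genes -0.52 (-1.06 to 0.0168), fat body genes 0.05 (-0.76 to 0.86) and salivary gland genes 1.28 (-1.12 to 3.68). A direct effect of vg on the gland, which the design names only through genotype, was not tested.

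The photoreceptor genes were lower in both groups with simj. In simj against lacZ a smaller eye part of the disc could account for this, since the retinal determination list was also lower, at -0.61 (95% interval -1.05 to -0.17). In vg_simj against lacZ the photoreceptor mean lay below the retinal determination mean by a difference of -0.75 (95% interval -0.96 to -0.53). The same difference in simj against lacZ was -0.20 (-0.41 to 0.00926). An equal loss of both lists is thus argued against in vg_simj. Whether a smaller eye part would lower both lists equally was not measured, so a smaller eye part stays open there too. Younger discs cannot be told apart from a smaller eye part, with a simj effect of -0.37 on the ecdysone response list (95% interval -0.97 to 0.23). A block of photoreceptor differentiation by simj, the effect that the genotype names, stays open and was not tested.

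Probe sets of Rnf11 (1 of its 2), mRpL45, lncRNA:CR32027 and Ykt6 and 7 other probe sets were called in the same direction in vg and in simj, both of which carry 1 UAS-lacZ copy against 2 in lacZ. Alleles of the UAS-lacZ stocks acting in proportion to copy number would place vg and simj midway, at 0.5, between lacZ at 0 and vg_simj at 1. The 5 probe sets that fell had a median position of 0.906 (SD 0.0397), which argues against such alleles for these 5 alone, since each fell more than 2-fold, and not for smaller falls, which were rarely called; alleles acting at a single copy were not tested. The 6 that rose had a median of 0.619 (SD 0.201), but single probe sets ranged from 0.241 to 0.825. Alleles acting in proportion would place each of them near 0.5. The median therefore cannot decide for the 6 together, and such alleles stay open for those. Because copy number follows genotype, a response shared by both transgenes also stays open.

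A difference in the vg effect between backgrounds, by the interaction test, drew attention to miple1 (-3.82), mthl8 (-4.41), CG31207 (-2.87), Rnf11 (-4.32) and an unnamed probe set (2.24) with limma. The other probe sets of Rnf11 (-0.48) and mthl8 (-1.44) did not pass this test (adjusted p = 0.995 for each). In miple1, mthl8 and CG31207 the vg and simj signals lay between those of lacZ and vg_simj. Alleles of the UAS-lacZ stocks acting in proportion to copy number were not tested for these genes and stay open. The 5 calls were lost without simj replicate 1, where the count was 0. The same test on lists called retinal determination (mean 0.43, adjusted p = 0.000438, adjusted p = 0.706 with an estimated correlation), photoreceptor (-0.18, adjusted p = 0.0277, adjusted p = 0.802 with an estimated correlation) and neuronal genes (-0.49, adjusted p = 9.9e-06, adjusted p = 0.706 with an estimated correlation). It called morphogenetic furrow (0.21, adjusted p = 0.0264, adjusted p = 0.725 with an estimated correlation), JNK and tissue damage (-0.23, adjusted p = 0.0157, adjusted p = 0.661 with an estimated correlation) and cell cycle genes (0.13, adjusted p = 0.0175, adjusted p = 0.757 with an estimated correlation). It also called cytosolic ribosomal (0.18, adjusted p = 0.000245, adjusted p = 0.786 with an estimated correlation), glial (-0.40, adjusted p = 0.00703, adjusted p = 0.653 with an estimated correlation) and ring gland genes (-0.80, adjusted p = 8.1e-07, adjusted p = 0.610 with an estimated correlation). With each array left out only the neuronal and ring gland calls held, and the retinal determination call was lost without vg_simj replicate 2.

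General knowledge ties the name of 4 control probe sets, left out of the comparisons, to the bacterial lac operon. Of these 1 had a signal of 719 ± 161 in simj, 128 ± 33.1 in lacZ, 110 ± 18.2 in vg and 3.55 ± 1.77 in vg_simj, the genotype with no UAS-lacZ. This signal did not follow the UAS-lacZ copy number, since simj with 1 copy lay far above lacZ with 2 copies and vg with 1 copy. The other control probe sets did not show that pattern, with means in lacZ, vg, simj and vg_simj of 95.7, 96.6, 105 and 86.2, of 28.9, 19.1, 20.4 and 19.5 and of 7.80, 0.800, 15.4 and 18.4.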

How the results depend on the processing

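The pseudocount of 64 and lists without vg and simj were chosen after seeing the data, and all other alternatives were planned. Without vg and simj 58 of the 66 list calls held. Of 156 gene calls under the naming rule 48 held under every alternative that kept their probe set and 0 reversed. The stricter filter kept the probe sets of only 99 of these calls, of which 81 held. Of 66 list calls 28 held under every alternative run on lists but the estimated correlation, with which 0 held. The cause of the changes below was not tested, except that the stricter filter tests fewer probe sets (5167) and that a left-out array leaves a lone array assumed to vary like the other groups. Calls numbered 44 without the intensity trend and 31 with only the groups compared in vg against lacZ. In simj against lacZ they were 18 with the stricter filter, 5 without the trend and 6 with only the groups compared. In vg_simj they were 176 with the stricter filter against lacZ, 39 with it and 41 with only the groups compared against vg, and 73 with it, 66 without the trend and 353 with only the groups compared against simj. The interaction had 2 with the stricter filter. Shared calls of the vg effect were 28 with the stricter filter, 23 without the trend and 22 with only the groups compared. Those of the simj effect were 10 with 0.1 times the pseudocount, 10 without a filter, 6 with the stricter filter, 2 without the trend and 1 with only the groups compared. With an array left out, calls ranged from 26 to 88 in vg and 1 to 34 in simj against lacZ, and in vg_simj from 156 to 337 against lacZ, 21 to 87 against vg and 28 to 174 against simj. The interaction ranged from 0 to 10, shared calls of the vg effect from 18 to 41 and of the simj effect from 0 to 11, and list calls from 61 to 74. With an array left out the log2 change of vg was 2.91 to 3.05 in vg against lacZ and 4.07 to 4.43 in vg_simj against simj, but 1.74 and 2.53 with the pseudocount of 64. That of simj was 0.67 to 1.27 and 0.52 to 0.76 with an array left out. Only 77 of the 156 gene calls held without vg_simj replicate 1 and 82 without vg_simj replicate 2. The list cytosolic ribosomal proteins: vg_simj vs lacZ reversed to -0.0498 without vg_simj replicate 1, and stood at 0.26 without vg_simj replicate 2. The fat body list in vg_simj against vg was -0.65 without vg replicate 2 and 0.47 without vg replicate 1. Quantile normalization and median centring moved the median change of all probe sets by at most 0.0493. Same-numbered replicates deviated together with r from 0.06 to 0.40, over 0.1 in 4 of 6 pairs of groups, so part of the variation follows the replicate number. The main model was fixed in advance without the replicate number and leaves this part in its spread. With the replicate number as a block, calls in vg_simj against simj rose to 213 and shared calls of the simj effect to 26, 156 of 156 gene calls held and 9 were gained, among them danr and phyl in simj against lacZ, and of the list calls 1 was lost and 4 were gained. Signals near background limit every fold in which a group lies near it, such as those of Jig, CG14852, Amnionless, Tsp68C and mthl8.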

Other observations

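The test of the replicate number reported here was chosen only after the values were seen, whereas the list tests were planned.

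Genes of cell division were slightly higher in vg_simj discs than in each other group, as a list of 45. The mean log2 change was 0.23 against lacZ (adjusted p = 8.82e-06, adjusted p = 0.706 with an estimated correlation), 0.16 against vg (adjusted p = 0.000785, adjusted p = 0.710 with an estimated correlation) and 0.20 against simj (adjusted p = 0.000461, adjusted p = 0.710 with an estimated correlation), with 39, 36 and 42 members positive. No member passed limma in these contrasts. Against lacZ the smallest p were those of mad2 (0.53 ± 0.12, adjusted p = 0.0658), Incenp (0.51 ± 0.12, adjusted p = 0.0740) and aurB (0.58 ± 0.14, adjusted p = 0.0821). The 38 ribosomal protein genes had a mean of 0.18 against simj (adjusted p = 0.00157, adjusted p = 0.802 with an estimated correlation), a call lost under quantile normalization and without vg_simj replicate 1. The ecdysone response list was lower in vg_simj than in vg (mean -0.43, adjusted p = 0.0130, adjusted p = 0.757 with an estimated correlation), with 0 of 23 members called and Blimp-1 at -1.82 ± 0.48 (adjusted p = 0.187), and the call was lost without vg replicate 2 and without vg_simj replicate 1.

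The cell death list was not called in vg (mean 0.46, adjusted p = 0.244, adjusted p = 0.719 with an estimated correlation) and 1 of its 13 members rose, skl. The signal of skl was 1146 ± 131 in vg and 1503 ± 290 in vg_simj, against 20.6 ± 2.76 in lacZ and 30.8 ± 13.1 in simj. The signal of Ilp8 was 16.9 ± 18.0 in lacZ, 259 ± 58.1 in vg, 161 ± 5.52 in simj and 650 ± 285 in vg_simj, while egr stood at 933 ± 9.40, 627 ± 36.8, 818 ± 31.7 and 373 ± 9.83. The heat shock list was not called in vg against lacZ (mean 0.04, adjusted p = 0.522, adjusted p = 0.804 with an estimated correlation).

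A model with the replicate number as a term called 44 probe sets that differed between replicates 1 and 2 of all groups, 34 higher and 10 lower in replicate 2. Chosen after their values were seen, Vha16-1 was higher in replicate 2 by 1.09 on the log2 scale (limma, adjusted p = 0.00725), grp by 1.23 (adjusted p = 0.0139) and DCP2 by 1.09 (adjusted p = 0.0158), and the cuticle genes Lcp65Ac and Lcp9 were at -2.32 and -3.74.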
